A study of Mus musculus with 3 samples.

How the data were processed

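Total RNA of kidney explants from mouse embryos at embryonic day 11.5, cultured for 48 h in 1 of 3 media, was extracted with a column kit, and 250 ng of it was turned into biotin-labelled cRNA, per the labels' protocols. It was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per medium. The dose of retinoic acid is not given in the sources used here. The deposited values are probe set intensities on a linear scale, from 3.84 to 17250. Per the submitters' processing notes they were made with Affymetrix Expression Console 1.1 and RMA, a method that subtracts background, equalises the distribution of the arrays by quantiles and summarises the probes of a probe set by median polish. The settings of that run are not given in the sources used here. Each column was matched to its sample by its name, and the sample to its medium by its label.

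All computation started from the log2 of the deposited values, with no pseudocount and no further scaling. Of 35556 probe sets, 21789 carried exactly 1 gene symbol in the platform annotation, 1621 carried several symbols, and 12146 had no name in the table used here. The last 2 kinds stayed out of the gene-level comparisons and are counted in the closing section. Gene identifiers of 21698 probe sets matched the RefSeq gene table (assembly GRCm38.p6), which was used for names only, and 0 symbols differed. No genome build goes with the array values, so no coordinates are given. A gene with several probe sets (999 genes) was represented by the one with the highest mean over the arrays, which gave 19938 genes. Where a gene had another probe set at or above the floor, the absolute disagreement between its log2 differences had a 95th percentile of 0.23 for retinoic acid against serum-free, 0.24 for serum-free against serum and 0.30 for retinoic acid against serum.

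The level floor was the median of all gene-level values, 7.12 on the log2 scale or 140 in intensity. In each comparison a gene was tested for size only, as at least 2-fold higher or lower with its higher value at or above the floor. With 1 array per medium there is no estimate of error, so no p-value was computed. The choices of groups, floor, size rule, gene lists, named genes and alternatives were fixed before the data were examined. The named genes were, per comparison, the 12 largest increases and 12 largest decreases among genes at or above the floor, leaving out gene models and families of near-identical copies. Srsy, a multi-copy gene that the written name patterns of this rule do not cover, was left out of the text as well. To these were added up to 4 members with the largest absolute difference of each list described, a fixed set of retinoid and kidney genes in all 3 arrays, and the 6 reversing genes with the largest smaller-of-both difference. Of that fixed set, 1 gene is not reported here. The values of Actg2 and Cnn1 in retinoic acid against serum-free were added after they were seen. Other reversing genes named were chosen after their values were seen, because they belong to a fixed list or to the fixed set.

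A total of 50 gene lists, covering the retinoid response, HOX genes, kidney cell types, other cell types that an explant can hold, and signalling, metabolic, stress and reference programmes, were each summarised by the median difference of the measured members. Each median was ranked among 10000 random lists of the same size drawn from the same 20 bins of mean level. A list symbol that was not found was looked up among synonyms. This put Nckap1 in place of H19 in the IGF axis list and Loxl3 in place of Loxl2 in the matrix list. Lists with fewer than 5 measured genes were not ranked, which left 49. A list was described where its percentile was under 2.5 or over 97.5, as a description of these arrays only.

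Many genes had exactly equal values on different arrays, since median polish over 3 arrays often returns the same value for a pair of arrays. Equal values made up 51.6% of genes for retinoic acid against serum-free, 45.4% for serum-free against serum and 46.5% for retinoic acid against serum. The procedure was tested on simulated data for retinoic acid against serum-free, with 19938 genes of 26 probes each passed through median polish. The only simulated error was independent probe noise with an SD of 0.3, with none shared by the probes of an array or between embryos. Among unchanged genes 77.8% came out exactly equal, more than the observed 51.6%, and 0 were called. Such noise is too small for 2-fold calls, so that 0 gives no rate of false calls for the arrays. Of 50 genes changed by 1.5 on the log2 scale, 100% were called, and their median returned difference was 1.39. A true difference of 0.5 came back as 0.43, one of 0.25 as 0.08, and one of 0.1 was returned as exactly 0 in 48% of 50 genes. In the simulation small differences were therefore understated, and an exact 0 is no measure of equal expression. How far small differences are understated on the arrays, which had fewer ties, was not established. A list of 25 simulated genes, whose differences were raised by 0.3 after median polish, came out at percentile 100. Since that shift did not pass through median polish, it does not show how a true shift of that size would rank. How many lists chance places outside the central range was not established, since ties hold the medians of simulated unshifted lists near 0.

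The alternatives were no floor, a floor at the 75th percentile of gene-level values (8.91), centring each array on its median, cyclic loess over the arrays (limma 3.58.1 in R 4.3.3, span 0.7, 3 iterations), the mean of a gene's probe sets, a 1.5-fold size rule, log2 of the intensity plus 32, and lists restricted to members at or above the floor. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.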

Results

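Gene expression was measured in mouse kidney explants, that is, embryonic kidneys taken from C57BL/6 embryos at embryonic day 11.5, when the ureteric bud has just begun to branch, and kept on porous Transwell filters for 48 h. The explants were grown in DMEM with 10% fetal bovine serum (serum), in DMEM with no serum (serum-free), or in serum-free DMEM to which retinoic acid, the active form of vitamin A, had been added (retinoic acid). RNA of each medium was hybridised to 1 Affymetrix Mouse Gene 1.0 ST array, giving 3 arrays in all. There were no replicates, so no difference below has an error or a test, and all values describe these 3 arrays. The number of arrays limits the precision. The median deposited intensity over all probe sets was 81.5 on the serum array, 85.5 on the serum-free array and 84.7 on the retinoic acid array. Values are given on the log2 scale, and a gene was counted as higher or lower when it differed by at least 2-fold with its higher value at or above a floor of 7.12. Where the lower value lies under the floor, the size of a difference is uncertain, since background takes up more of a low intensity. The series title names its aim as the identification of genes that respond to retinoic acid in kidney development.

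The first comparison asked which genes differed when retinoic acid was added to serum-free medium. The largest difference was in Ecm1, which encodes a secreted matrix protein and was 40.6-fold higher with retinoic acid (12.52 against 7.17). Cyp26b1, which encodes an enzyme that degrades retinoic acid, was higher by 3.65 (10.25 against 6.60, which lies under the floor). Dhrs3, which encodes a reductase that turns retinaldehyde back to retinol, was 10.0-fold higher (12.05 against 8.73), and Rarb, which encodes a retinoic acid receptor, was 7.72-fold higher (11.37 against 8.43). The largest decreases were in Cited1, a marker of uninduced nephron progenitors, at -2.13, and in Dbh, which encodes the enzyme that makes noradrenaline, at -2.13.

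In all, 106 genes were at least 2-fold higher and 62 at least 2-fold lower with retinoic acid, of 10111 genes at or above the floor. At least 4-fold, 20 were higher and 2 were lower. Other large increases were in Tnfsf13b, which encodes a cytokine of B cells, by 3.82, in the hormone gene Sst (somatostatin) by 3.22, in the neuropeptide receptor gene Npffr2 by 2.82, and in the casein gene Csn3 by 2.62. Tgm5, a transglutaminase gene, was higher by 2.45, Cntn1, a neural adhesion gene, by 2.42, Lrrc7 by 2.32 and the cytokine gene Il33 by 2.23. With 32 added to the intensities, which damps low values, the differences became 3.24 for Tnfsf13b, 2.03 for Npffr2 and 2.02 for Csn3. Among the genes that were lower, the chemokine gene Ccl11 differed by -1.89, the connexin gene Gja5 by -1.89, the chromogranin gene Chga by -1.85, the tachykinin receptor gene Tacr3 by -1.81 and Tfap2b by -1.70. Vcam1 differed by -1.67, Emp1 by -1.66, Vgll3 by -1.63 and the potassium channel gene Kcnk9 by -1.61.

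A list of 25 measured retinoic acid response genes had a median difference of 0.33, with 6 members at least 2-fold higher and 0 at least 2-fold lower. Stra6, which encodes a membrane receptor that takes up vitamin A, was higher by 1.56 (10.70 against 9.14). Cyp26a1 stayed below the floor on every array, at 5.57 with retinoic acid and 4.42 without. Not every retinoid gene was higher. Crabp2, which encodes a retinoic acid binding protein, differed by -0.49, and Aldh1a2, which encodes the enzyme that makes retinoic acid, by -0.95 (10.54 against 11.50). The 3-prime HOX genes, which pattern the hindbrain and anterior trunk and many of which are induced by retinoic acid in other embryonic tissues, had a median of 0.43 over 14 genes, of which 11 had differences above 0 and 2 were at least 2-fold higher. Hoxc4 was higher by 1.19 and Hoxa4 by 1.02, and the values for Hoxc5 and Hoxa2 were 0.87 and 0.80.

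Among the lists for kidney cell types, the ureteric bud tip had a median of 0.33 over 17 genes. The receptor tyrosine kinase gene Ret, which drives branching, was 2.83-fold higher (9.92 against 8.42). Adamts18 was higher by 1.62 and Lhx1 by 1.28, while Met differed by -1.02. Wnt11, a target of Ret signalling in the tip, differed by only 0.33, and Gdnf, the Ret ligand made by the mesenchyme, by -0.15. Cap mesenchyme nephron progenitors had a median of -0.10 over 24 genes, or -0.16 over those at or above the floor. Of the 24, 2 were at least 2-fold lower and 1 at least 2-fold higher. Its members went both ways, with Cited1 at -2.13 and Meox2 at -1.52 but Meox1 at 1.81. Osr1 differed by -0.97, and Six2, which keeps progenitors undifferentiated, by -0.86 (10.39 against 11.26). Foxd1, the marker of renal stroma progenitors, differed by 0.08.

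Of 13 smooth muscle and ureter mesenchyme genes, 2 were at least 2-fold lower with retinoic acid, Acta2 (smooth muscle actin) at -1.39 and Tagln (transgelin) at -1.32. In the same list 1 was at least 2-fold higher, Car3 at 1.02, and the value for Tshz3 was 0.95. The contractile genes Actg2 at -1.40 and Cnn1 at -1.02 were also lower by that size, but their values lay under the floor on both arrays (7.07 and 5.67 for Actg2, 6.79 and 5.77 for Cnn1, without and with retinoic acid). The list as a whole had a median of -0.05, which became 0.01 when only the 7 members at or above the floor were kept, a step that leaves out Actg2 and Cnn1 among others. Targets of the transcription factors SRF and YAP had a median of -0.11 over 19 genes, with Tpm2 at -0.95 and Ccn2 at -0.71. Immediate early genes had a median of -0.16 over 18 genes, with Nr4a1 at -0.83 and Dusp1 at -0.63, and 0 of them differed 2-fold.

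Markers of other cell types also differed between these arrays. Macrophage genes had a median of -0.37 over 18 genes, with Cd68 at -1.16 and Mrc1 at -1.02 but Pf4 at 1.07. Endothelial genes had a median of -0.19 over 18 genes, with 16 differences below 0 and 0 genes at least 2-fold lower. The largest were in Sox18 at -0.57 and Cdh5 at -0.35. Genes of cholesterol biosynthesis had a median of 0.15 over 20 genes, with Nsdhl at 0.47. Those of fatty acid synthesis had a median of 0.18 over 14 genes, with Scd1 at 0.74 but Fads3 at -0.75.

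Against 10000 random lists of the same size and matched expression level, 16 of 49 lists lay outside the central range of the random medians, 8 above and 8 below. Besides the lists just named, these were 5 lists with medians from -0.06 to 0.04, namely mitosis, p53 targets, canonical histone genes, oxidative phosphorylation and housekeeping reference genes. The matched ranges were narrow because 51.6% of genes had exactly equal values on the retinoic acid and serum-free arrays, so the size of a list's median says more than its percentile.

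The embryos' sex was not given in the labels, and sex-specific transcripts differed between the arrays. Xist, which is transcribed from the inactive X chromosome of female cells, was at 10.84 in serum, 11.48 in serum-free medium and 9.79 with retinoic acid. The Y-linked gene Eif2s3y ran the other way, at 8.38, 7.46 and 8.64 in the same order, as did Kdm5d at 7.74, 7.21 and 8.40 and Uty at 7.93, 7.29 and 8.38. In retinoic acid against serum-free, the 3 Y-linked genes are counted among the 106 higher genes and Xist among the 62 lower ones. A difference in the sex of the embryos between these arrays cannot be told apart from an effect of the medium.

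**Figure D1:**
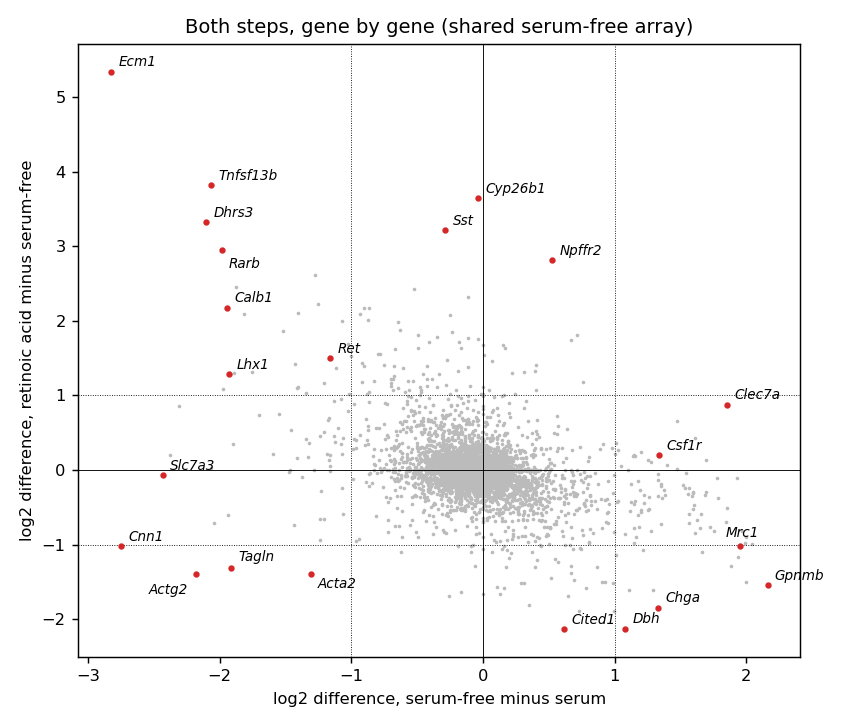
Each point is a gene with at least 1 value at or above the floor. The horizontal axis is its log2 difference between serum-free and serum, the vertical axis that between retinoic acid and serum-free, and dotted lines mark a 2-fold difference; Ecm1 stands at -2.82 and 5.34, and Cnn1 at -2.75 on the horizontal axis.

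The second comparison asked what differed when serum was left out. Without serum, 14 of 18 macrophage genes were at least 2-fold higher. On the other side, 8 of 22 early nephron genes and 4 of 13 smooth muscle genes were at least 2-fold lower. The largest increase was in Gpnmb, a glycoprotein gene of macrophages and other phagocytic cells, which was 4.47-fold higher (2.16). The largest decreases were in Ecm1, 7.08-fold (-2.82), and in Cnn1, which encodes the smooth muscle protein calponin, at -2.75 with a serum-free value under the floor (6.79). Genes that were higher with retinoic acid in the first comparison were among those lower here, with Dhrs3 at -2.10 and Rarb at -1.98.

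Of 10156 genes at or above the floor, 89 were at least 2-fold higher without serum and 71 at least 2-fold lower. At least 4-fold, 2 were higher and 10 were lower. The largest increases after Gpnmb were in Ms4a6c at 2.04, Ms4a6d and Ms4a7 at 3.99-fold each, the galectin gene Lgals3 at 1.99, Cd180 at 1.97, the purinergic receptor gene P2ry13 at 1.93, the scavenger receptor gene Cd36 at 1.88 and the lectin receptor gene Clec7a at 1.85. The largest decreases also took in the amino acid transporter gene Slc7a3 at -2.43, the carbonic anhydrase gene Car4 at -2.38, the transporter gene Slco4c1 at -2.31 (-1.72 with 32 added to the intensities), Tnfsf13b at -2.07, Igfbp7 at -2.06, the arginase gene Arg2 at -1.98 and Ccn2, a target of YAP, at -2.05.

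The macrophage list had a median of 1.37, or 2.58-fold, and 14 of its 18 genes were at least 2-fold higher without serum, with 0 lower. Mrc1 was higher by 1.95, Cd68 by 1.94, and the complement genes C1qc and C1qb by 1.86 and 1.69. Liver X receptor targets, which export cholesterol and are also active in macrophages, had a median of 0.30 over 9 genes, with Apoe higher by 1.54, Abca1 by 1.47 and Abcg1 by 1.37 but Abcg5 at -0.67. Endothelial genes had a median of 0.42 over 18 genes, with Cdh5 at 0.81 and Esam at 0.63, and 0 of them reached 2-fold. Genes of neurons and glia had a median of 0.40 over 13 genes, with Dbh higher by 1.08 and the values for Th and Fabp7 at 0.91 and 0.82.

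Smooth muscle and ureter mesenchyme genes had a median of -0.73 over 13 genes, and 4 of them were at least 2-fold lower without serum. Cnn1 differed by -2.75, Actg2 by -2.18, Tagln by -1.91 and Acta2 by -1.31. Targets of SRF and YAP had a median of -0.26 over 19 genes, with Ccn2 at -2.05, Ccn1 at -1.24 and Myl9 at -1.21. The median was -0.09 over 25 stroma genes, of which 4 were at least 2-fold lower, and -0.08 over 30 matrix genes. Under cyclic loess scaling they were -0.06 and -0.05. The matrix list held Loxl3 in place of Loxl2. Lox, which cross-links collagen, differed by -1.44, Fbln5 by -1.16 and Fhl2 by -1.13, while Postn was at 0.55.

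Of the kidney epithelial lists, genes of the pretubular aggregate and early nephron had a median of -0.54 over 22 genes. Of these, 8 were at least 2-fold lower and 0 at least 2-fold higher, led by Lhx1 at -1.93, Papss2 at -1.89, the nephron inducer Wnt4 at -1.43 and Greb1 at -1.21. The ureteric bud tip had a median of -0.52 over 17 genes, with Slco4c1 at -2.31, Ret at -1.16 and the value for the Ret co-receptor gene Gfra1 at -0.75. Wnt11 stood at -0.67. The ureteric bud trunk had a median of -0.17 over 20 genes, with Calb1 at -1.94 and Elf5 at -1.40. Six2 was at 0.23, Foxd1 at -0.22, Gdnf at -0.10 and Aldh1a2 at 0.13.

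The retinoic acid response list had a median of -0.07 over 25 genes. Over the members at or above the floor it was -0.24. Of the 25, 3 were at least 2-fold lower, namely Dhrs3, Rarb and Ret, and the value for Stra6 was -0.80. Cyp26b1 was at 6.63 in serum and 6.60 without it, a difference of -0.03, Crabp2 differed by -0.06, and Cyp26a1 was below the floor in both media, with a difference of -0.58. The 3-prime HOX genes had a median of -0.12 over 14 genes, with Hoxc4 at -0.57.

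Genes of cholesterol biosynthesis had a median of -0.75, with 20 of 20 differences below 0 and 2 genes at least 2-fold lower. The isomerase gene Idi1 differed by -1.32, Insig1 by -1.18, Msmo1 by -0.99 and Nsdhl by -0.93. Fatty acid synthesis genes had a median of -0.31 over 14 genes, with the desaturase gene Scd1 at -1.70 and the malic enzyme gene Me1 at -1.38. Targets of ATF4, the transcription factor of the amino acid response, had a median of -0.47 over 23 genes, with Slc7a3 at -2.43, Chac1 at -1.47, the asparagine synthetase gene Asns at -1.23 and Cth at -1.12. Mitosis genes had a median of -0.24 over 25 genes, all with differences below 0, but 0 of them reached 2-fold, and the largest difference was in Bub1 at -0.43. BMP targets had a median of -0.22 over 12 genes, with Smad6 at -0.66.

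Of 49 lists, 28 lay outside the central range of matched random lists, 9 above and 19 below. The lists not yet named among these had medians from -0.18 to 0.13. They were adrenal cortex and gonad, with 2 of 12 genes at or above the floor, erythroid cells, canonical histone genes, FOXO targets, the unfolded protein response, heat shock, p53 targets, the interferon response, the IGF axis and ribosome biogenesis. Over members at or above the floor the median became -0.54 for adrenal cortex and gonad, from -0.18, and 0.24 for erythroid cells, from 0.05. It became 0.04 for p53 targets, from 0.13, and 0.01 for FOXO targets, from 0.06. For the interferon response it became 0.09, from 0.01. With 32 added to the intensities, adrenal cortex and gonad had a median of -0.07. For the IGF axis the median (0.01, or 0.04 under cyclic loess) and the mean (-0.06) differed in sign. That list held Nckap1 in place of H19, so its values are not those of the IGF axis alone. Klf9 at -1.75 and the selenoprotein gene Selenop at 1.01 had the largest differences of the FOXO list.

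**Figure D2:**
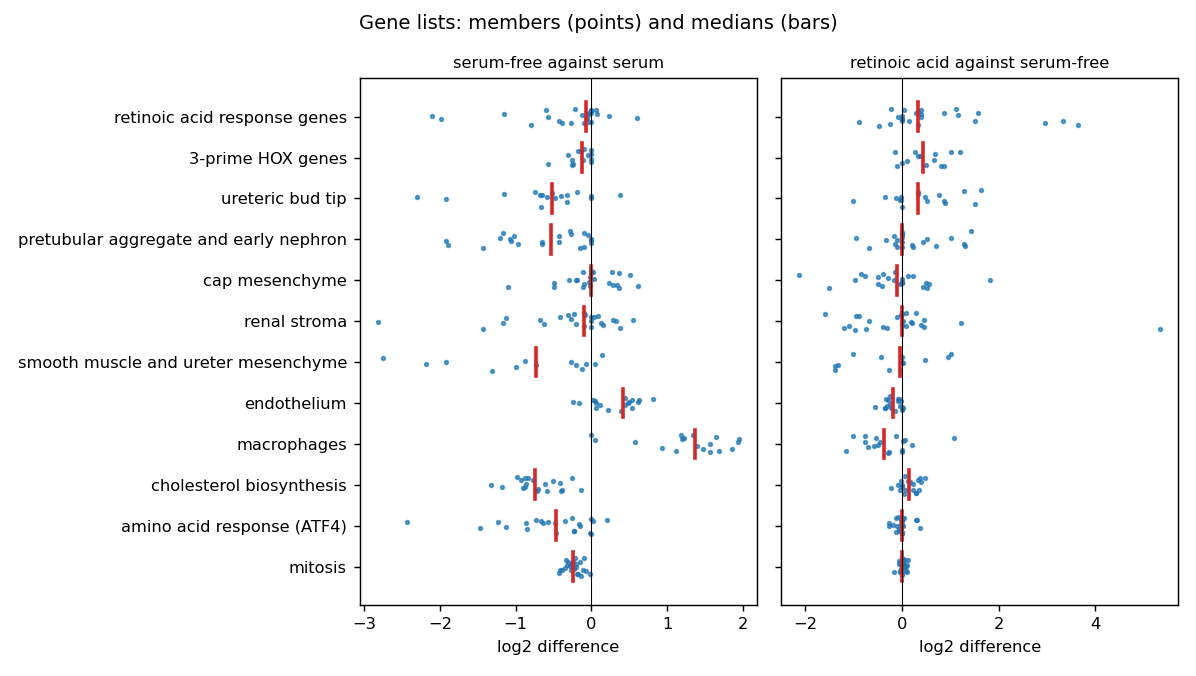
Each point is a measured gene of the list named on the left, and each red bar is the list's median. The horizontal axes are log2 differences; without serum the macrophage median is 1.37 and the cholesterol biosynthesis median -0.75, and with retinoic acid the 3-prime HOX median is 0.43.

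The third comparison set explants in serum-free medium with retinoic acid against those in serum. Cyp26b1 was higher by 3.61 with retinoic acid than in serum, Npffr2 by 3.34 and Sst by 2.93. The serum values of Cyp26b1 (6.63) and Npffr2 (4.54) lay under the floor, and with 32 added to the intensities Npffr2 differed by 2.28. Genes of contractile cells were among the lowest, with Cnn1 at -3.77, Actg2 at -3.58, Tagln at -3.23 and Acta2 at -2.70. The retinoic acid values of Cnn1 (5.77), Actg2 (5.67) and Tagln (6.52) lay under the floor, and with 32 added to the intensities Cnn1 differed by -3.16 and Actg2 by -2.95. For Acta2 the values were 12.42 in serum, 11.11 in serum-free medium and 9.72 with retinoic acid. Of 18 macrophage genes, 6 were at least 2-fold higher than in serum.

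Here 106 genes were at least 2-fold higher and 83 at least 2-fold lower, of 10169 at or above the floor. The lectin receptor gene Clec7a was higher by 2.73, Ecm1 and the chemokine gene Ccl6 by 2.52 each, Timd4, a receptor gene of macrophages, by 2.41, Lrrc7 by 2.21, the sterol exporter gene Abca1 by 2.13, the kinase gene Tec by 1.94 and Cntn1 by 1.90. Ccn2 differed by -2.75, Map3k7cl by -2.54, Slc7a3 by -2.50, the potassium channel subunit gene Kcne3 by -2.18, Lox by -2.18, Car4 by -2.17, Igfbp7 by -2.04 and Tfap2b by -1.96.

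Retinoic acid response genes had a median of 0.19 over 25 genes, or 0.29 over those at or above the floor, with Dhrs3 higher by 1.22 and the values for Rarb, Stra6 and Cyp26a1 at 0.96, 0.76 and 0.58. The 3-prime HOX genes had a median of 0.28 over 14 genes, led by Hoxa4 at 0.76. Ret was at 0.34, Wnt11 at -0.35, Gdnf at -0.25, Crabp2 at -0.55, Foxd1 at -0.14 and Aldh1a2 at -0.82. The ureteric bud tip list had a median of -0.08 and lay within the matched range. The ureteric bud trunk list lay below its matched range, with a median of -0.28 over 20 genes and 13 differences below 0. Its median for serum-free against serum was -0.17. Cap mesenchyme genes had a median of -0.22 over 24 genes, with Cited1 at -1.52, Meox2 at -1.23, Six2 at -0.63 and Meox1 at 1.32. Early nephron genes had a median of -0.53 and a mean of -0.47 over 22 genes, against -0.54 and -0.67 for serum-free against serum, and 2 of them were at least 2-fold lower than in serum, against 8 there. These were the Wnt inhibitor gene Dkk1 at -1.92 and Lfng at -1.12. With retinoic acid against serum-free, the list had a median of 0, with 4 genes at least 2-fold higher and 0 lower.

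The macrophage list had a median of 0.93 over 18 genes, with Csf1r, which encodes the receptor for the macrophage growth factor, higher by 1.54, Fcgr3 by 1.49 and C1qa by 1.46. Liver X receptor targets, set beside it, had a median of 0.41 over 9 genes, with Apoe 2.82-fold higher. Endothelial genes had a median of 0.12, and genes of neurons and glia one of 0.16, or 0.41 over members at or above the floor, with Stmn2 higher by 1.73 and Chrna3 by 1.16 but Dbh at -1.05. Smooth muscle and ureter mesenchyme genes had a median of -0.30 over 13 genes, and SRF and YAP targets one of -0.30 over 19 genes, with Ccn1 at -1.90 and Myl9 at -1.86. Stroma genes had a median of -0.14 over 25 genes, with Tnc at -1.72 and Lum at -1.43. Cholesterol biosynthesis genes had a median of -0.54, with 20 of 20 differences below 0 and 0 genes at least 2-fold lower. ATF4 targets had a median of -0.47 over 23 genes, with Asns at -1.51 and Chac1 2.82-fold lower. Mitosis genes had a median of -0.25 over 25 genes, with 22 differences below 0 and 0 genes at least 2-fold lower. In all, 26 of 49 lists lay outside the matched range, 10 above and 16 below. Those not named for this comparison had medians from -0.19 to 0.17.

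The last comparison counted genes that differed at least 2-fold without serum and at least 2-fold in the opposite direction once retinoic acid was added. Among the 71 genes lower without serum, 22 were higher with retinoic acid, and 19 of these 22 ended within 2-fold of their serum level. The other 3 ended at least 2-fold above it. Ecm1 went from 10.00 in serum to 7.17 without it and 12.52 with retinoic acid. Dhrs3 had 10.83, 8.73 and 12.05 in the same order, Tnfsf13b 7.90, 5.83 and 9.65, Rarb 10.41, 8.43 and 11.37, and the calcium-binding protein gene Calb1 11.67, 9.73 and 11.91. Tgm5 had 7.65, 5.78 and 8.24. Ret had 9.58, 8.42 and 9.92, and Wnt4 8.92, 7.49 and 8.92. In the opposite direction, 12 of the 89 genes higher without serum were lower with retinoic acid, among them the macrophage genes Cd68, Mrc1, Cd36 and Gpnmb and the genes Dbh and Chga.

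Because both steps used the same serum-free array, opposite signs can arise from that array's error alone. Independent lists of these sizes would share 0.415 and 0.550 genes. In 100 simulations of 3 unchanged arrays, with the error of each drawn from the differences between the retinoic acid and serum arrays, a median of 21.5 genes (13 to 32) went down and then up, against 22 observed. A median of 33 (20 to 45) went up and then down, against 12 observed. In the same direction, 2 genes went down in both steps, against a simulated median of 0 (0 to 1). Up in both steps were 0 genes, against a simulated median of 0 (0 to 2). The covariance of the steps, with the sign of the serum step turned, was 0.0208 against a simulated 0.0303, and their correlation across genes, which are not independent, was 0.41 against 0.50. Both simulated values were fixed by giving the arrays equal errors of that size, so neither comparison tests reversal. The simulated error contains any real difference between those arrays, and 1 array per medium leaves no way to split the shared array, so the count of reversing genes has no independent check here.

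**Figure D3:**
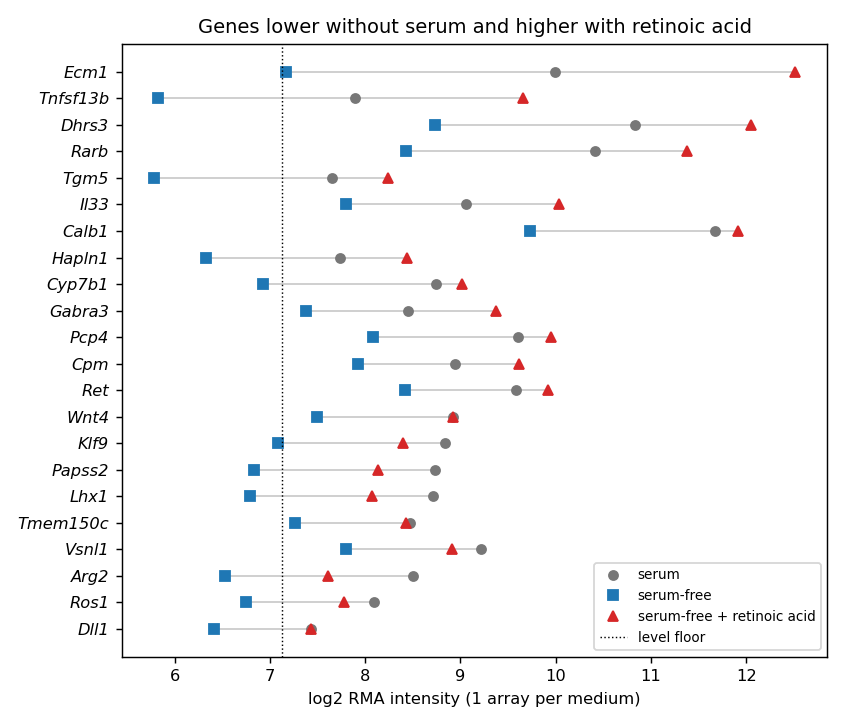
Log2 RMA intensity of the 22 genes that were at least 2-fold lower without serum and at least 2-fold higher with retinoic acid, with 1 point per array and gene. The grey circle is serum, the blue square serum-free medium, the red triangle serum-free medium with retinoic acid, and the dotted line the floor of 7.12; Ecm1 spans 7.17 to 12.52.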

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

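All tests of explanations in this part were chosen after the results were seen. The values below come from probe sets that the gene comparisons did not use, since they had no gene name here or carried several. In retinoic acid against serum-free, 23 probe sets with no gene name differed at least 2-fold, 13 higher and 10 lower. In the same comparison 1 probe set annotated to several genes differed at least 2-fold. It belongs to Gbp2 and Gbp2b, guanylate-binding protein genes induced by interferon, and was higher with retinoic acid by 2.94. Its values were 7.84 with retinoic acid and 4.90 without, which lies under the floor, so the size of the difference is uncertain. In serum-free against serum, 116 probe sets with no gene name differed at least 2-fold, 99 higher and 17 lower without serum. In that comparison 49 probe sets annotated to several genes differed at least 2-fold, and all 49 were higher without serum.

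Most of these 49 belonged to families with many near-identical copies. The small nucleolar RNA family Snord116 gave 24, with a median difference of 1.13, and the Y-linked testis gene family Ssty gave 9, with a median of 1.35. The other 16 were 4 of the Speer family (1.58), 2 of the Vmn family (1.34) and 10 of other kinds (1.19). With retinoic acid against serum-free, the medians were 0.39 for Snord116 and 0.60 for Ssty but -0.38 for Speer, -0.51 for Vmn and -0.38 for the others. Against serum, the retinoic acid array had medians of 1.52 for Snord116, 1.96 for Ssty, 1.21 for Speer, 0.82 for Vmn and 0.80 for the others. More RNA from male embryos in the serum-free array is argued against, because Eif2s3y, Kdm5d and Uty had a median of -0.65 there. On the retinoic acid array these Y-linked genes stood above both other arrays. More RNA from male embryos in that array therefore stays open for the Y-linked Ssty family. A general rise of low signal is argued against for Snord116, whose median level in serum was 9.42, above the floor of 7.12. The other groups had medians in serum from 5.72 to 6.22. For them such a rise could not be tested, since the quantile step of RMA makes the low values of the arrays alike. Most of the 24 Snord116 probe sets had identical values on every array (9.42 in serum, 10.55 in serum-free medium, 10.94 with retinoic acid). They therefore do not count as separate measurements. A single signal read by near-identical probes of all copies may account for the like differences within a family. These had an SD of 0.02 over 24 Snord116 probe sets and of 0.27 over 45 Ssty probe sets. The probe sequences were not used here, so for Ssty this stays open, as does a difference between the media for both families.

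The macrophage genes were higher without serum as a group. A larger share of macrophages in that RNA is a candidate explanation. Of the members with both values at or above the floor, 12 of 12 were higher by at least 0.5, from 1.12 to 1.94. This outcome was known beforehand, since 14 of the 18 members were at least 2-fold higher, so it does not test that explanation. Of the 18 members, 0 belong to another fixed list. C1qb went from 9.53 to 11.22 and Laptm5 from 9.50 to 11.06. The central range of medians of random lists matched on level was -0.08 to 0, against 1.37 for the macrophage list. The quantile step of RMA equalises the distributions of the arrays and so holds such random medians near 0. That range therefore does not test a scaling difference that moves all genes of like level together. With retinoic acid, 11 of 14 such members had lower values than without it, from -1.16 for Cd68 to 0.20 for Csf1r, and whether a smaller share of macrophages is the whole of that difference stays open, since 1 array per medium gives no error for such a range. A change in macrophage state, and an effect of the medium on macrophage number, stay open and untested.

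The last pattern is the 22 genes lower without serum and higher with retinoic acid. They include all 3 genes of the retinoic acid response list that were at least 2-fold lower without serum (Dhrs3, Rarb and Ret). They also include 4 of the 8 such genes of the early nephron list (Dll1, Lhx1, Papss2 and Wnt4), and 11 of the 22 lay in some fixed list. The serum-free values of Dll1 (6.42), Lhx1 (6.79) and Papss2 (6.84) lay under the floor, and both steps use them, so their sizes are uncertain. Error of the shared serum-free array falling on genes at random stays open: when 22 of the 71 genes lower without serum were drawn at random, some list held at least 4 of them in 21.6% of 10000 draws, and a median of 12 lay in some list. A smaller share of ureteric bud epithelium as a whole, large enough for 2-fold decreases, is argued against by the trunk list. Of its 17 members with 1 or both values at or above the floor, 14 were not lower by 0.5, and the other 3 were Calb1 (-1.94), Elf5 (-1.40) and Krt19 (-0.75). The trunk list's median of -0.17 was known when this count was chosen, so the count adds no separate test. A smaller difference in that share stays open. The ureteric bud tip list had a median of -0.52, with 14 of 17 members lower, so a smaller share of the tip alone stays open too. A response to retinoids in serum and in the added retinoic acid may underlie part of the pattern, as an untested hypothesis.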

How the results depend on the processing

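All alternatives were fixed before the data were examined. Median centring, cyclic loess and the mean of a gene's probe sets left all 8 counts within 1.5 times, all 70 list medians within 0.1 and all 346 values of named genes within 0.25 on the log2 scale, with 0 changes of sign in a called value. As both scalings scarcely moved any value, they say little about stability. The counts also stayed within 1.5 times with no floor. The stricter floor, which keeps fewer genes, gave 55 higher and 26 lower for retinoic acid against serum-free, 40 and 32 for serum-free against serum, and 46 and 40 for retinoic acid against serum, with 10 genes down then up and 7 up then down. The 1.5-fold rule, wider by construction, gave 244 and 196, 204 and 210, and 250 and 289 in the same order, with 62 down then up and 67 up then down. Adding 32 to the intensity gave 7 genes up then down and left the other counts within 1.5 times. It also moved 46 of 346 named genes and 5 of 70 list medians, since it shrinks differences of dim genes. Keeping only members at or above the floor moved 12 of 70 list medians by more than 0.1 and reversed 1, the smooth muscle and ureter mesenchyme list in retinoic acid against serum-free, at 0.0103, where the step leaves out, among others, Actg2 and Cnn1, both lower with retinoic acid. Signal near the floor limits the fold sizes of genes that are dim on 1 array, such as Tnfsf13b and Npffr2. No paired analysis was possible because each medium has 1 array.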

Other observations

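The genes and families in this part were chosen after their values were seen, and no test was run on them. Of the 106 genes at least 2-fold higher with retinoic acid than in serum-free medium, 10 belong to families of neurotransmitter and neuropeptide receptors, ion channels and neural adhesion proteins. They were Npffr2 (2.82), Cntn1 (2.42), Grik4 (2.10), Kcnk2 (2.07), Npy1r (2.01), Gabra3 (1.99), Lrfn5 (1.78), Htr2b (1.76), Slitrk1 (1.54) and Gria4 (1.12). The channel genes Kcnk9 (-1.61) and Cacng3 (-1.50) were lower. In serum-free against serum, 1 gene of these families was higher (Kcnk9, 1.29) and 2 were lower (Gabra3, -1.07, and Kcne3). The families were picked because some of their members had large differences, so no enrichment follows.

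The following values are of genes known from catecholamine-producing cells. In serum, serum-free medium and retinoic acid, Dbh stood at 8.21, 9.30 and 7.17, Th, which encodes the enzyme that starts catecholamine synthesis, at 6.69, 7.60 and 6.10, Chga at 8.13, 9.45 and 7.61, and the transcription factor gene Phox2a at 7.06, 7.60 and 6.88. The neuronal gene Stmn2 was at 9.75, 10.15 and 11.49, and Chrna3, a nicotinic receptor gene, at 7.52, 8.09 and 8.68.

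Tagln stood at 9.76, 7.84 and 6.52 in serum, serum-free medium and retinoic acid, and Actg2 at 9.25, 7.07 and 5.67. The transcription factor genes Tbx18, of the renal stroma list, and Tshz3, of the smooth muscle and ureter mesenchyme list, were at 9.43, 8.75 and 9.97 for Tbx18 and at 9.76, 9.50 and 10.45 for Tshz3.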
